A study of Caenorhabditis elegans with 4 samples.

How the data were processed

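The samples were 2 MRG-1 ChIP libraries and 2 input DNA libraries from N2 early embryos, per the labels. Embryos were crosslinked in 1.85% formaldehyde for 30 min, and chromatin was sonicated in 14 rounds for ChIP and in 9 rounds for input by a different procedure, per the labels' protocols. The peak lists carry the genome build WormBase WS220, per the file headers. The submitters' processing notes name BWA and ce10 without a version or role. The source column of the deposited lists names MACS for the replicate lists and MACS v2 for the series-wide list. The caller's settings, the control used, read filters and the way the replicates entered the series-wide list are not given in the sources used here. The unit of the deposited values is the authors' peak score, which no header defines. The lowest score is 50 in both replicate lists and 1.3 in the series-wide list. Scores therefore served only to rank and filter peaks within a list and to correlate replicate lists. The replicate lists were called per sample, and the series-wide list is treated as a pooled list with no replicate.

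All lists were used as deposited. Peaks on mitochondrial DNA, 1 in replicate 2 and 4 in the series-wide list, were left out of every comparison of the report. Chromosome lengths were not in the files, so the span of a chromosome was taken as the end of its last peak in any list, 100 Mb in total for 6 chromosomes. Coverage is the share of a span or window inside peaks. Read depth per sample is unknown, and exact binomial intervals cover counting error only.

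Overlap meant at least 1 shared bp, and p-values came from 10000 circular shifts of one list along each chromosome. Score correlations used the pair of peaks with the most shared bases. X and autosomal windows of 1 Mb were compared by 100000 two-sided permutations, as were width and rank of single peaks. Centre and arms were the middle 50% and the outer 25% on either side. Spacing was compared with 1000 random placements without overlap. Shared shares on X and autosomes were compared by two-sided Fisher's exact tests, and within 10 score bins by a Mantel-Haenszel odds ratio. The threshold was 0.05. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

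The named regions were fixed by a rule before the data were examined: the 10 shared peaks with the highest mean score rank percentile, the 5 widest shared peaks, the strongest shared peak per chromosome, the 3 most and 3 least covered autosomal 1 Mb windows and the most covered X window. Tests and most alternatives were also fixed then. Alternatives were stricter score thresholds, other overlap rules, windows and boundaries, each replicate left out and the series-wide list. The first look at the lists showed coverage, peak counts, centre-to-arm ratios and shared shares by chromosome before the explanations in the closing section were written down. In the alternatives, 1000 circular shifts were used, and 10000 permutations for medians in the stricter lists.

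The position of peaks relative to genes, the share of genes with a peak and 22 gene lists had been planned. They were not run, because no annotation of WS220 was given and coordinates of the table supplied, which is for WBcel235, were not used. Only its number of protein-coding genes per chromosome was used.

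The procedures were tested on simulated data, 20 lists of 3158 placed peaks each, with overlapping ones removed. With a planted X-to-autosome ratio of 0.2 and a centre-to-arm ratio of 1.5, the recovered means were 0.220 and 1.44, and the window test passed 0.05 in 20 of 20 lists. With both at 1 it passed in 0 of 20. These lists lack the closer spacing of the real peaks, so they do not show how far window p-values are too small. With 70% of peaks planted as shared, 71.7% were found, and with 0% the overlap was 17.8% against 17.5% by shifts, with 2 of 20 lists under 0.05.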

Results

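MRG-1 binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in early embryos of wild-type *Caenorhabditis elegans* (strain N2, mixed males and hermaphrodites) at 20 °C. MRG-1 is a chromodomain protein related to mammalian MRG15 that is supplied by the mother and needed for germ cell development. The series held 4 samples, 2 MRG-1 ChIP libraries made with the antibody SDQ3927 and 2 input DNA libraries. Peak lists for the 2 ChIP libraries and a list for the whole series were analysed, and values of the input libraries were not analysed here. The labels number the ChIP libraries 1 and 2 without saying whether they came from separate cultures, so the spread between them may be technical. Read depth is unknown for every list. Coordinates are those of WormBase WS220, 1-based, and values with an error are the mean ± SD of the replicate lists (n = 2).

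The replicate 1 list held 3158 nuclear peaks with a median width of 2360 bp, and the replicate 2 list held 2875 nuclear peaks with a median width of 2514 bp. They covered 10.0 Mb and 9.67 Mb, which was 10.0% and 9.64% of the chromosome spans. Peaks of 5000 bp or more numbered 534 in replicate 1 and 544 in replicate 2 and held 39.3% and 43.0% of the covered bases. The series-wide list held 14479 nuclear peaks with a median width of 331 bp that covered 8.88 Mb, and 70 of them, with 4.99% of the covered bases, were 5000 bp or more.

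How far the replicate libraries marked the same regions was examined first. Of the replicate 1 peaks, 2319 of 3158 (73.4%, exact 95% interval 71.86 to 74.97) overlapped a replicate 2 peak by at least 1 bp, and 2293 of 2875 replicate 2 peaks (79.8%, 78.2 to 81.2) overlapped a replicate 1 peak. The lists had 7.61 Mb in common, with a Jaccard index of 0.630. Circular shifts along the chromosomes gave an overlap of 19.9% and 21.2% of peaks on average, and the one-sided shift p was 1e-04 in each direction, the smallest that 10000 shifts can give. Shared peaks were wider and scored higher than the others. In replicate 1 their median width was 2942 bp against 1506 bp, and in replicate 2 2955 bp against 1434 bp. A wider peak meets the 1 bp rule more easily, so part of the width difference is built into the rule. Across 2165 shared pairs the authors' peak scores had a Spearman's rho of 0.81 and a Pearson's r of 0.79 on the log scale, and coverage of 97 windows of 1 Mb had a rho of 0.91. These relations are across peaks or windows, which are not independent replicates. When midpoints had to lie within 250 bp, 39.1% of replicate 1 peaks and 43.0% of replicate 2 peaks were shared, against 1.69% and 1.86% by shifts.

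The shared regions with the highest scores were autosomal domains of several kilobases. Scores near 3100 are tied in both lists, and 8 shared peaks ranked above the tie: 2 on chromosome I, 2 on IV, 2 on V, 1 on II, 1 on III and 0 on X. Another 25 were tied for the last 2 of the 10 places, 7 on I, 7 on IV, 5 on III, 3 on II, 3 on V and 0 on X. The order among the 10 is loose, since 7 of them had a score of exactly 3100 in replicate 2. The first of these spanned chromosome I from 1697333 to 1703203 in replicate 1 and from 1697364 to 1703230 in replicate 2. The strongest on chromosome III spanned 1616194 to 1622443 in replicate 1, where its score of 3233 was the highest of the list. On chromosome IV the strongest spanned 652153 to 658636, on V 8460445 to 8466889 and on II 7045756 to 7055196, all in replicate 1. The strongest shared peak on X spanned 15806865 to 15811630, with a score rank percentile of 94.3 in replicate 1 and 77.3 in replicate 2, while the strongest peak of each autosome had a mean percentile of 98.7 or more. By the mean width of the replicates, the widest shared domain lay on chromosome I from 4377553 to 4395082 in replicate 1 (17530 bp). Its score ranked near the middle in replicate 1, at a percentile of 47.3, and low in replicate 2, at 13.8. The next by mean width lay on chromosome IV from 379686 to 398484 (18799 bp in replicate 1 and 15356 bp in replicate 2), with percentiles of 86.6 and 75.1. No annotation of this build was given, so the regions are reported by position and not by gene.

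MRG-1 had earlier been described on autosomes and low on the X chromosome, so the X was compared with the autosomes. MRG-1 peaks covered 2.13% ± 0.602 of X and 11.5% ± 0.432 of the autosomes (SD, n = 2). Chromosome III was covered most, at 17.2% ± 0.467, followed by I at 15.0% ± 0.506, II at 11.7% ± 0.440, IV at 9.59% ± 0.408 and V at 6.50% ± 0.368. This order was the same in replicate 1, in replicate 2 and in the series-wide list. The X-to-autosome ratio of coverage was 0.144 in replicate 1 and 0.229 in replicate 2, with a mean of 0.186 ± 0.0595, and it was 0.175 in the series-wide list. By the mean of the replicates, the most covered 1 Mb window of X, from 4 to 5 Mb, reached 3.80% ± 0.981, and 75 of the 80 autosomal windows exceeded it. Within each replicate, 77 and 68 autosomal windows exceeded the highest X window, which in replicate 1 was the first Mb, at 4.07%. The difference over 1 Mb windows had a two-sided permutation p of 1e-05 in each replicate, the smallest that 100000 permutations can give, and X ranked lowest of 6 chromosomes, where an exact rank p cannot go below 0.167. Neighbouring windows are not independent, so the window p is too small. In the replicate lists the ratio was lower among high-scoring peaks: it was 0.0667 among the 50% of peaks with the highest scores and 0.0264 among the top 1000 of each list, where X had 7 and 8 peaks, whereas in peaks per Mb it was 0.339 ± 0.142.

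**Figure D1:**
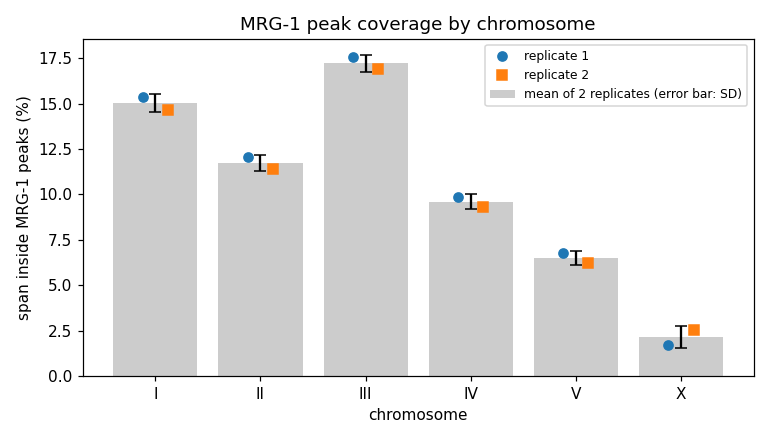
Share of each chromosome's span inside MRG-1 peaks (%), by chromosome. Bars show the mean of the 2 replicates with the SD, and circles and squares show replicates 1 and 2; the mean is 17.2% on chromosome III and 2.13% on X.

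Peaks on X were narrower and ranked lower in the replicate lists. The median width on X was 1518 bp against 2434 bp on autosomes in replicate 1, and 1445 bp against 2665 bp in replicate 2. The median score rank percentile was 27.1 against 51.8 in replicate 1 and 29.6 against 53.2 in replicate 2. In the series-wide list the order of the ranks was the opposite, with a median percentile of 64.9 on X and 48.8 on autosomes. The replicate and series-wide lists name the caller differently, and no header defines their scores. Their ranks may therefore not measure the same quantity. X peaks were still narrower in the series-wide list, at 300.0 bp against 334 bp. Two-sided permutation tests over peaks gave Benjamini-Hochberg adjusted p-values from 1.5e-05 to 0.00262 over these 6 comparisons, and peaks are not independent replicates. The mean width difference was -1285 bp among the 50% of peaks with the highest scores (larger permutation p = 0.0145) and -685 bp among the top 1000 of each list, where it rests on 7 and 8 X peaks and did not pass the threshold (0.537).

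Autosomal centres are rich in conserved genes and the arms in repeats, so the middle 50% of each chromosome was compared with its outer 25% on either side. On the autosomes the centres were covered more than the arms, at 14.3% ± 1.31 against 8.69% ± 2.17 (SD, n = 2). The centre was higher on 5 of 5 autosomes in each replicate and in the series-wide list. The two-sided exact sign p was 0.0625, the smallest that 5 autosomes allow. The replicates differed in size, with an autosomal centre-to-arm ratio of 1.304 in replicate 1 and 2.12 in replicate 2 (1.71 ± 0.580). The ratio was highest on chromosome V, at 2.20 ± 0.903, and lay between 1.54 and 1.88 on the other autosomes. In peaks per Mb the ratio was 1.01 in replicate 1 and 1.56 in replicate 2, and in replicate 1 the median peak width was 2963 bp in the centres and 2037 bp in the arms.

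**Figure D2:**
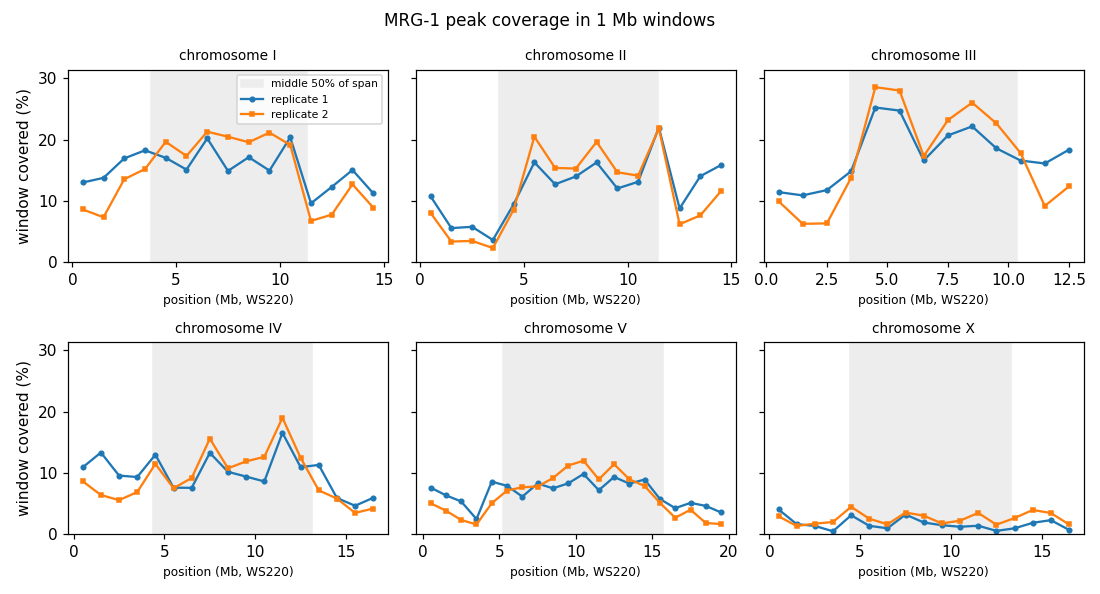
Share of each 1 Mb window inside MRG-1 peaks (%) against position (Mb, WS220), with 1 panel per chromosome. Circles are replicate 1, squares replicate 2 and grey the middle 50% of the span; the highest window, on chromosome III from 4 to 5 Mb, is covered at 25.2% and 28.5%.

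The X chromosome showed no such excess of coverage in its centre. Its centre-to-arm ratio was 0.996 in replicate 1, 1.08 in replicate 2 and 0.867 in the series-wide list, and for coverage it was the lowest of the 6 chromosomes in each list. In peaks per Mb the ratio of X was 1.00 in replicate 1, above those of chromosomes I, II and IV, and 0.968 in replicate 2. On the log2 scale of coverage X lay below the mean of the autosomes by a difference of -0.70 ± 0.43 (SD, n = 2), with -0.40 in replicate 1 and -1.01 in replicate 2. The exact rank p for the lowest of 6 cannot go below 0.167.

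**Figure D3:**
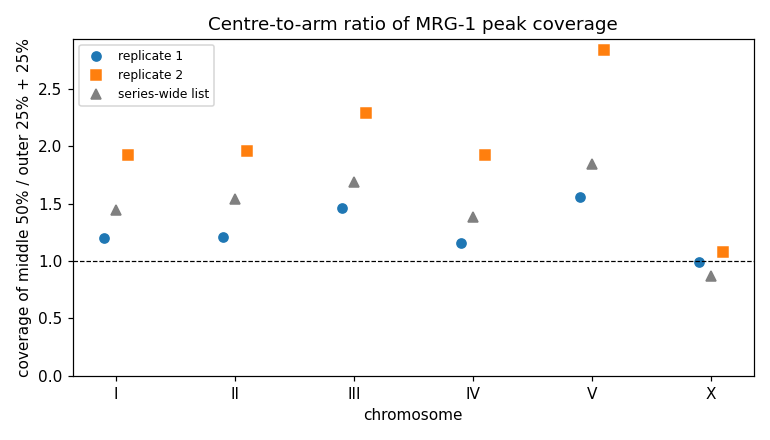
Coverage of the middle 50% of each chromosome divided by that of its outer 25% on either side. Circles, squares and triangles are replicate 1, replicate 2 and the series-wide list, and the dashed line marks a ratio of 1; the autosomes lie above it and X lies at 0.996, 1.08 and 0.867.

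The arms of single autosomes were unequal. The left arm of chromosome II was covered at 0.420 ± 0.0299 of its right arm and that of chromosome III at 0.610 ± 0.0393. On chromosome IV the left arm was covered more, with a ratio of 1.50 ± 0.114, as on V at 1.26 ± 0.0813 and I at 1.12 ± 0.0669. On X the replicates went in opposite directions, at 1.23 and 0.794. The most covered autosomal windows all lay on chromosome III, from 4 to 5 Mb (26.9% ± 2.35), from 5 to 6 Mb (26.4% ± 2.31) and from 8 to 9 Mb (24.1% ± 2.74). The least covered were chromosome V from 3 to 4 Mb (2.04% ± 0.619), V from 19 to 20 Mb (2.62% ± 1.34) and II from 3 to 4 Mb (2.95% ± 0.929). No test was run on the arm ratios.

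Peaks lay closer to the next peak than in uniform random placements along each chromosome. The median distance to the next peak was 9179 bp in replicate 1 against 16364 bp for random placements, and 13273 bp against 19008 bp in replicate 2. The one-sided p was 9.99e-04 in both, the smallest that 1000 placements can give. In the series-wide list the median was 620.0 bp against 3618 bp.

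The series-wide list was compared with the replicate lists because no source used here states how it was combined. Of its 14479 nuclear peaks, 42.4% overlapped peaks of both replicates, 14.2% of replicate 1 only, 11.8% of replicate 2 only and 31.5% of neither. The peaks overlapped by both replicates held 66.5% of the list's bases. Those overlapped by neither were narrow, with a median width of 228 bp, and held 14.8%. In the reverse direction 98.6% of replicate 1 peaks and 99.7% of replicate 2 peaks overlapped a series-wide peak, with a median of 2 series-wide peaks each. Of the bases in these replicate lists, 67.0% and 68.3% lay inside series-wide peaks. On X, 49.2% of the series-wide peaks overlapped neither replicate, against 30.4% on autosomes. Such peaks held 33.9% of the series-wide bases on X and 14.0% on autosomes. These differences were not tested.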

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

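Signal on mitochondrial DNA lies outside the comparisons of the report. The replicate 2 list had 1 mitochondrial peak, from 2 to 13639, that covered 13638 bp, with a score rank percentile of 58.7. The series-wide list had 4 mitochondrial peaks that covered 12676 bp. The replicate 1 list had 0. No input values were analysed here, so the level in control samples is not known, and no explanation was tested.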

How the results depend on the processing

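The alternatives added after the data were seen were peaks per protein-coding gene, scores without values of 3100 or more, and centres and arms of shared peaks. Of 66 alternatives, 54 kept the direction and either the side of the threshold or a value within the spread used for comparison, 10 moved further, 1 lost its call and 1 reversed. The 54 include 6 that could not have moved further, since leaving out 1 of 2 replicates cannot move a mean by more than 1 SD. These concern the centre-to-arm ratio, its difference between X and autosomes and the left-to-right ratio, and without them 48 of 60 kept. Some of the 48 were also partly fixed. For X coverage, width, score rank and spacing, the p-value compared was the larger of the 2 replicates. Leaving out a replicate could change the direction there but could not lose the call. The X-to-autosome ratio stayed under 1 and past the threshold in the 10 tested alternatives, from 0.0264 to 0.229 in coverage and at 0.339 in peaks per Mb. In peaks per protein-coding gene, which had no test and is another measure, it was 0.460. Windows of 100 and 500 kb could change only the p-value and not the ratio. The overlap of replicates stayed past the threshold in 6 of 6 for each list. Both lists were judged by the same p-value, the larger of the 2 directions. Autosomal centre-to-arm ratios ran from 1.29 to 2.12 over 8 alternatives. The score rank of X peaks minus that of autosomal peaks was -24.1 percentile points in the replicate lists and 16.1 in the series-wide list. The scores of these lists may not measure the same quantity, and the cause was not settled by the test reported under other observations. The width difference of -1068 bp was -685 bp among the top 1000 peaks, where X had 7 and 8 peaks. The X-minus-autosome log2 centre-to-arm difference was -2.09 with the same few peaks. The score correlation was 0.84 with 50% of each peak shared and 0.71 among the 50% of peaks with the highest scores. It was 0.66 among the top 1000 and 0.79 without scores of 3100 or more. A narrower range of scores is part of the construction of the last 3. The share of series-wide peaks overlapped by both replicates was 40.3% with 50% of the shorter peak required, 5.19% with 50% of each peak, which the widths of the lists (medians of 331 bp against 2360 and 2514 bp) largely fix, 37.6% among the top 50% of each list and 63.8% among the top 1000; for the others the cause was not tested. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no values here. The alternatives for position relative to genes, genes with a peak and gene lists were not run, since these need an annotation of WS220. Depth is unknown, so what it limits cannot be stated.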

Other observations

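The regions in this paragraph and the next, and the tests of gene number, of coverage level and of chromosome ends, the Fisher's tests of shared shares and the odds ratios against centre or arm peaks were chosen after the values were seen. The longest gap between peaks coincided in the replicates on chromosomes I, IV and V and lay elsewhere on II, III and X. Both replicates left the same long stretch of chromosome IV free of peaks, from 15648377 to 16381754 in replicate 1 (733 kb) and from 15648395 to 16381155 in replicate 2 (733 kb). Another lay on chromosome V, from 2778977 to 3563419 in replicate 1 (784 kb) and from 2696780 to 3563992 in replicate 2 (867 kb). On chromosome I the longest gap was 280 kb in both, starting at 11612583 and at 11612566. On X it was 762 kb in replicate 1, from 15850062 to 16611924, and 465 kb in replicate 2, from 5298802 to 5763516. The series-wide list has peaks within these stretches, and its longest gap on IV was 336 kb.

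Peaks reached the first 1000 bp of 5 of 6 chromosomes in replicate 1 (I, II, IV, V and X), of 3 in replicate 2 (I, II and X) and of 4 in the series-wide list. The hypothesis that this was chance position was tested by circular shifts, which gave one-sided p-values of 3e-04 in replicate 1 and 0.0306 in replicate 2. Right ends could not be tested, because each span was taken to end at its last peak. Mapping of repeated sequence at chromosome ends was not tested.

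X had few peaks and little coverage. In covered bases per protein-coding gene (WBcel235 gene numbers) the X-to-autosome ratio was 0.196 and 0.310, far from the 1 that gene number alone would give, so the lower number of genes on X does not account for the coverage. For the number of peaks per gene the ratio was 0.324 in replicate 1, below the lower of the bounds set. In replicate 2 it was 0.596, between the bounds, so the replicates differed and the test did not decide. X had 56.4 peaks per 1000 genes against 94.3 on V in replicate 1, 90.8 against 79.3 in replicate 2 and 312 against 383 in the series-wide list. A score threshold that hides weak X peaks stays open as a part of the shortage. In peaks per Mb the ratio was 0.475 and 0.737 among the 25% of peaks with the lowest scores. Among the 25% with the highest it was 0.0178 and 0.0065, but X had only 3 such peaks in replicate 1 and 1 in replicate 2. Peaks covered less of X than of the autosomes within each library. Whether low binding of MRG-1 on X accounts for this was not tested against the input, whose values were not analysed here.

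The replicates differed by region: coverage in replicate 2 exceeded that in replicate 1 in 32 of 41 autosomal centre windows, 1 of 39 arm windows and 15 of 17 X windows, and X peaks of replicate 2 were shared less often than its autosomal peaks (45.6% against 83.0%, two-sided Fisher's exact test p = 2.97e-36, adjusted 5.95e-36 over 2 tests), while in replicate 1 73.4% were shared on both (p = 1), the autosomal value being a mixture of 88.2% in centres and 58.4% in arms (78.3% and 90.2% in replicate 2). Peaks are not independent replicates, so the Fisher's p for replicate 2 is too small. Replicate 1 had 154 X peaks against 248 in replicate 2, and 113 were shared in each list. The lower share of replicate 2 X peaks therefore follows in part from these counts, which had already been seen. On autosomes replicate 1 had more peaks, 3004 against 2627. On the arms, an equal number of peaks did not remove the difference in coverage between the replicates. The replicate 2 to replicate 1 ratio of centre-to-arm values was still 1.55 with 1000 peaks each (1.63 in full). Among windows covered at 8 to 16%, arms lay below centres by a log2 difference of -0.75 (permutation p = 1e-05, the smallest possible). The difference was thus also present at like coverage. That test used windows already seen to differ, so its outcome was likely in advance. Neighbouring windows are not independent, so its p is too small. For X, the first test written, with 1000 peaks each, gave a ratio of 1.07, which by itself met the prediction for peak number. It rests on 7 and 8 X peaks and decides nothing, so a difference in strictness stays open there. The full lists had 1.61 times as many X peaks and 0.875 times as many autosomal peaks in replicate 2. Within score bins the odds ratio of being shared on X was 0.227 (0.161 to 0.319) in replicate 2. It was 0.420 (0.294 to 0.599) against centre peaks and 0.0761 (0.0495 to 0.117) against arm peaks. Score alone therefore did not account for the lower share. Peak width, peak counts and the coverage of X in replicate 1 (1.70% against 11.8% on autosomes) were not adjusted for, so no other cause is assigned. In replicate 1 the odds ratio was 2.47 (1.67 to 3.67), but this rested on the arms: 5.66 (3.69 to 8.68) against arm peaks and 0.786 (0.516 to 1.20) against centre peaks. Differences in chromatin, embryo stage or control between the libraries may remain as explanations, and the labels do not separate them.

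X peaks ranked below autosomal ones in the replicate lists and above them in the series-wide list. A candidate explanation is that the series-wide list splits broad autosomal domains into several peaks of lower score. After series-wide peaks under 1000 bp apart were joined, with the highest score kept, X regions still ranked 6.61 percentile points above autosomal ones (permutation p = 0.00103), down from 16.1. That met the prediction against splitting. With 2000 bp the difference was -1.32 (permutation p = 0.536), so the outcome depends on the joining distance. Keeping the highest score raises regions joined from more peaks. Autosomal regions held 2.60 peaks on average against 1.26 on X with 1000 bp, and 3.59 against 1.34 with 2000 bp. Part of the fall is therefore built into the joining, so this test cannot decide and the explanation stays open. The caller named and the score scale also differ between the replicate and series-wide lists, and whether this explains the opposite order was not tested. No biological explanation was tested.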
